A study of Mus musculus with 2 samples.

How the data were processed

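The deposited files describe DNase-seq of liver from 1 group of C57BL/6J mice in constant darkness, with 1 biological replicate and 2 technical-replicate libraries per the labels. Per the labels the assembly is mm10. Per the read-me texts deposited with each library, every list was made from an alignment that pooled both libraries, in 2 processing runs on different filtered alignments. Aligner, peak caller, footprint caller and their versions are not given in the sources used here, and the read-me texts themselves hold no measurement. No deposited column held values of a single library, and the number of columns of per-sample values left unused was 0.

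The first run gave a peak list, a list of hotspots (broader regions of raised cleavage) and a track of cleavage rates. The second run gave a permissive and a stringent peak list, a footprint list and a second track. Peak height in the 3 deposited peak lists is a signal. In the first-run list it is a whole number without scaling for depth, and in the second-run lists it is a whole multiple of 1 constant step, both read from the values. The deposited hotspot score runs from 13 to 1000 (median 69) and is 10 times the deposited −log10 false discovery rate, which runs from 1.30 to 100 (median 6.86), read from the values and from the authors' column description. The deposited tracks of cleavage rate hold a p-value type of measure, the false discovery rate at each listed position, and list only positions below 0.05. The footprint list carries the deposited p-value type entry 0.01 for every footprint, its false discovery threshold. How the lists were thresholded limits what can be seen: a gene without a peak had none in the list, which sets no upper limit on its accessibility.

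The GRCm38.p6 assembly and the GENCODE M21 annotation, which use mm10 coordinates, served as reference, and 0 peaks lay past a chromosome end. Positions are 1-based. A peak was assigned to a promoter when its midpoint lay within 1 kb of any annotated start site, otherwise to exon, intron or intergenic DNA. For each of 21938 protein-coding genes the largest promoter height (0 if none) and the number of distal peaks within 50 kb were taken from the first-run list. Both were taken over all annotated start sites of the gene, so genes with more or wider spaced start sites had more sequence searched. The random lists described below were not matched on this. The 24 gene lists with 292 genes, the 32 consensus strings, the groups, the main tests and most alternatives to try were chosen before the data were examined. Later choices are named below, among them most tests of explanations and the search for strings in clock promoters. For each gene list, the median was placed among 10000 random lists of the same size matched on 10 classes of promoter CpG observed over expected; a list outside the central 95% was read as standing apart. Lists overlap in 6 genes (Ass1, Cyp1a2, Cyp2e1, Cyp7b1, Des and Pck1), and some promoter peaks serve neighbouring genes, such as those of Abcg5 and Abcg8. With 1 sample, no p-value across genes was computed and no comparison between conditions was possible.

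Consensus strings were searched on both strands without mismatch. Strings with their centre in a footprint were counted against those in the other bases of the permissive peaks. These peaks come from the same run as the footprints. Each string was also compared with up to 20 reordered versions that held as many CG steps (C followed by G). Versions not found on both sides of a comparison were left out. The same strings were counted per kb in distal and promoter peaks of the first-run list, and in windows 1 kb away from distal peaks. Named genes were all members of the clock list, the 4 genes of each other list with the largest promoter height, up to 2 genes of each list without a promoter peak in alphabetical order, and the 10 promoter and 10 distal peaks with the largest heights; some genes that this rule names are not reported here. Matches of peaks elsewhere in the reference were sought with blastn 2.17.0 (at least 90% identity over at least 50 bp), with 500 random autosomal peaks for comparison.

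Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. On simulated data, overlaps computed here and by bedtools differed by 0, a planted promoter share of 30% was recovered as 30%, and a motif ratio planted at 2.91 came out at 2.90. Of 200 random lists of 12 genes left unchanged, 4% fell outside the central 95%, and of 200 such lists with heights raised 4-fold, 65% lay above it (21938 genes), so a list within its range can still hold raised promoters.

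Alternatives were an overlap of 50%, peaks at or above the median height, the other peak lists, promoters of 500 bp or 2.5 kb, windows of 20 kb or 100 kb, unmatched random lists, 20 bp flanks as background for footprints, distal or promoter peaks alone, and thresholds of 0.05 and 0.001 for the tracks. Added after seeing the data were the basic transcript set for peak location, the first-run list for strings in footprints, and the other lists and higher peaks for chromosomes. Alignments and signal tracks were not used here.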

Results

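DNase-seq was performed on liver of adult C57BL/6J mice, 8–10 weeks old, that had been kept for 66 hours in constant darkness and were sampled at circadian time 54. In this assay the enzyme DNase I digests DNA that nucleosomes leave exposed, so that sites of frequent cleavage mark accessible chromatin. Short stretches of low cleavage inside them (footprints) are read as places where a protein covered the DNA. Strings in footprints are called protected below, but whether a protein covered them was not tested. The series held 1 group with 1 biological replicate, from which 2 technical-replicate libraries were made. Each deposited list pooled the reads of both libraries, so no value per library was obtained and every value describes this 1 liver sample without replicates. Intervals given with shares and ratios are exact Clopper-Pearson 95% intervals, which cover counting error only. Read totals were not used here, so the depth per library is unknown; the depth-scaled peak heights of the second run were whole multiples of 0.00382 in 100% of peaks (within 0.02 of a step), and the highest peak stood at 21298 steps.

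The first question was how much of the liver genome was accessible, and where. The list used for most results held 256769 peaks, nearly all 150 bp wide, with a median height of 120 and a range of 7 to 22394, and covered 38.5 Mb or 1.41% of the genome. As nearly all peaks had the same width, this coverage follows from their number. The broader hotspots of the same run covered 3.68%. Promoters, here positions within 1 kb of an annotated start site, held 19.6% of the peaks (19.5–19.8), against 6.05% of random genome positions, and their peaks were the highest, with a median height of 223. Introns held 43.7% of the peaks (median height 115), intergenic DNA 31.9% (median 92) and exons outside promoters 4.77% (median 117). Intergenic DNA was the class with fewer peaks than random positions, of which 52.3% were intergenic. The promoter share was 31.0% when promoters were taken as 2.5 kb around start sites.

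Of 21938 protein-coding genes, 15370 had at least 1 promoter peak (70.1%, 69.5–70.7), and the median of the largest promoter height over all of them was 467. The share rose with promoter CpG content, from 21.3% of genes in the lowest 10% to 96.9% in the highest 10%. Olfactory and vomeronasal receptor genes, which serve chemosensory neurons, had a promoter peak in 108 of 1466 cases (7.37%, 6.08–8.83). Gene lists were therefore compared with 10000 random lists of protein-coding genes of the same size, matched on promoter CpG content, and the percentiles below describe these pooled libraries.

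As a list, promoters of circadian clock genes had higher peaks in this liver than matched random lists. All 24 genes of the clock list had a promoter peak, and the median of their largest heights was 2210.5, at percentile 99.96 of the random lists, whose central 95% ran from 603.5 to 1673. The highest belonged to Nr1d2 and Nr1d1, which encode the REV-ERB repressors of the clock. The Nr1d2 peak (14:18239156–18239305, mm10) reached 4435 and lay 103 bp upstream of a start site, measured from its midpoint, and the Nr1d1 peak (11:98775376–98775525) reached 3610 at 117 bp upstream. Per1, a light- and hormone-responsive repressor of CLOCK:BMAL1, had a peak of 3419 upstream of its first exon (11:69094896–69095045), and the upstream peak of the output gene Dbp (7:45704876–45705025) reached 3339. Arntl, which encodes BMAL1, had an upstream peak of 3253 (7:113207196–113207345).

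Other clock genes had heights of 2878 for Tef, 2786 for Cry2, 2617 for Wee1, 2287 for Hlf, 2270 for Per2 and 2156 for Ciart. Bhlhe40 (1883), Per3 (1792), Usp2 (1721), Npas2 (1658), Csnk1d (1325), Nfil3 (1208), Bhlhe41 (1181) and Cry1 (1087) had lower promoter peaks. The lowest in the list were Rora (952), Clock (884), whose highest promoter peak lay in an intron (5:76303916–76304065), and Csnk1e (500), whose peak lay in a coding exon next to an internal start site (15:79425556–79425705). Clock genes also had many distal peaks, meaning peaks more than 1 kb from any start site. Their median was 25 within 50 kb (percentile 99.99, median over all protein-coding genes 11), with 67 around Rora and 49 around Nr1d1. These counts cover the windows around all start sites of a gene. The random lists were not matched on start sites, and whether this adds to the percentile was not tested.

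**Figure D1:**
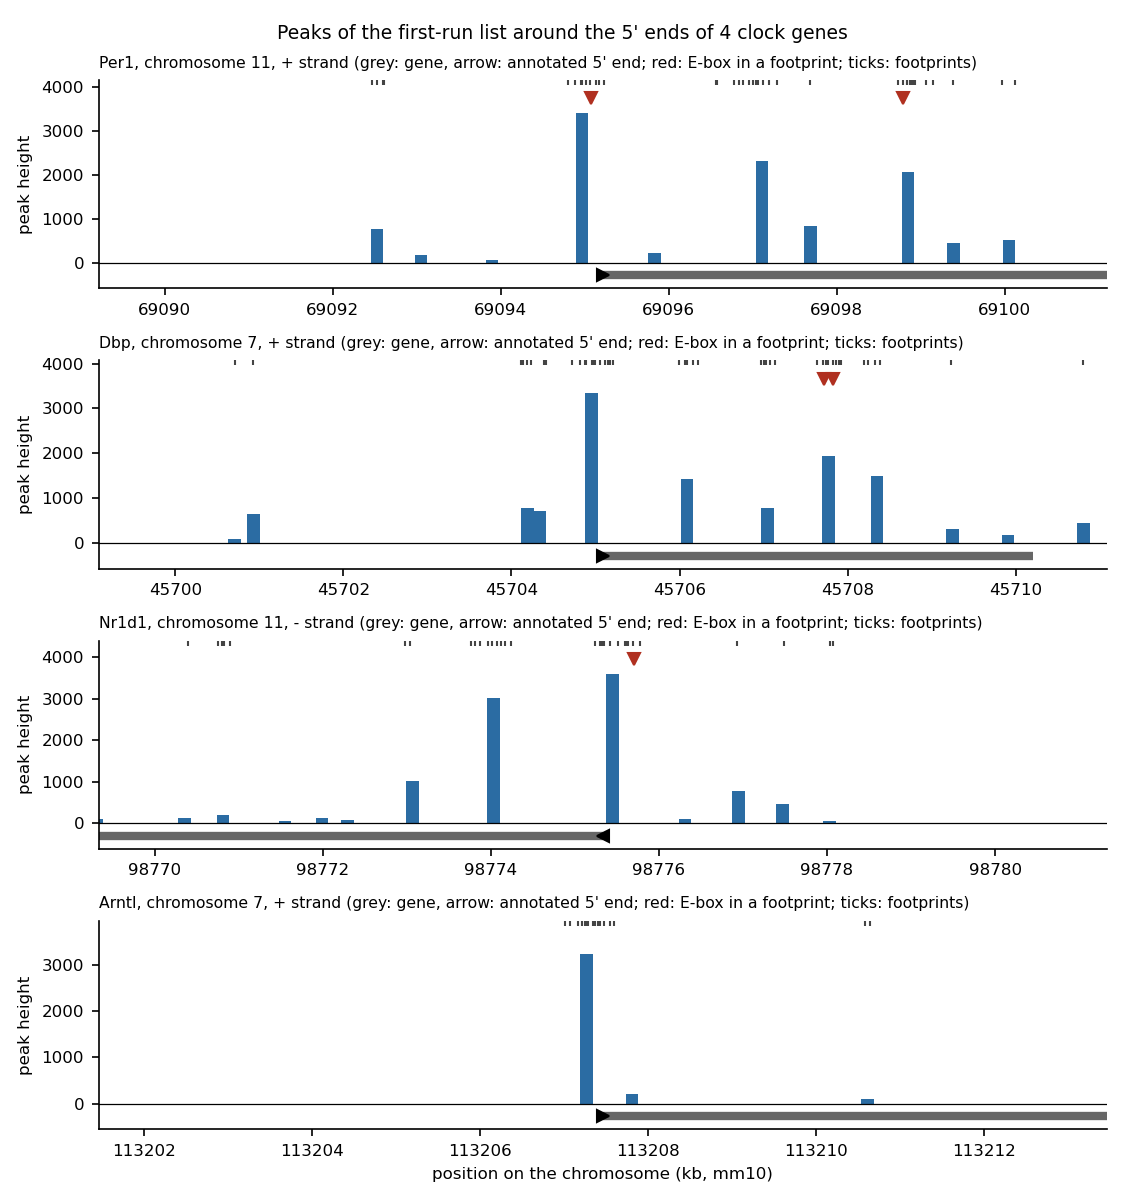
Maps of the first-run peaks (blue bars, height as deposited) around the annotated 5′ ends of Per1, Dbp, Nr1d1 and Arntl against position in kb, with footprints as ticks, genes in grey and E-box strings inside footprints of promoter peaks as red triangles. The highest promoter peak of each gene, 3419 for Per1, 3339 for Dbp, 3610 for Nr1d1 and 3253 for Arntl, stands just upstream of the annotated 5′ end.

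Genes of hepatocyte function had accessible promoters in every member of the lists. The list of secreted plasma proteins had a promoter peak in 22 of 22 genes with a median height of 2071 (percentile 100), led by the complement gene C3 at 3266 (17:57228156–57228305, upstream), the fetuin gene Ahsg at 2898 (16:22891856–22892005, intron), the fibrinogen gene Fgg at 2813 (3:83007656–83007805, untranslated exon) and Apoh at 2387. Liver transcription factors had a peak in 21 of 21 genes with a median of 1942 (percentile 100), with the largest at Nfia (3879, in an intron at 4:97773296–97773445), Nr5a2 (3347), the bile-acid-induced repressor gene Nr0b2 (2956) and Ppara (2839). Both lists lay far above their random lists, whose upper bounds were 228 and 1244. Distal peaks were dense as well, with medians of 37.5 and 41 per gene (percentile 100 in both).

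The lists of gluconeogenesis and fasting, lipogenesis, bile acid and cholesterol, and xenobiotic genes also lay above their random lists. The urea cycle list, given below, did not. Gluconeogenesis and fasting genes had a peak in 14 of 14 promoters with a median of 2318.5 (percentile 100), and the largest was at Angptl4, an inhibitor of lipoprotein lipase, which reached 4197 in an intron (17:33779416–33779565). Pcx (3346), Cpt1a (3118) and Pck1 (2953, 2:173152716–173152865, upstream) followed. Lipogenesis genes had a peak in 15 of 15 with a median of 2295 (percentile 100), among them Acly at 3269 (11:100527936–100528085, upstream), Mlxipl at 3017 and Thrsp at 2663. Bile acid and cholesterol genes had a peak in 18 of 18 with a median of 1833.5 (percentile 99.97). Hmgcs1 reached 3037 and Srebf2 2963, and the divergent sterol transporter genes Abcg5 and Abcg8 shared 1 peak of 2698 (17:84682956–84683105). Xenobiotic genes had a peak in 14 of 14 with a median of 1490.5 (percentile 99.99), with 3561 at Por, the reductase that supplies cytochromes P450, 2740 at Gstm1, 2379 at Gsta3 and 2243 at Sult1a1. Median numbers of distal peaks in these lists were 36.5, 33, 29.5 and 39.5, each at percentile 100.

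Genes of both ends of the liver lobule carried promoter peaks. Periportal genes had a peak in 10 of 10 with a median of 1846.5 (percentile 99.9), with 4112 at Uroc1, an enzyme of histidine breakdown (6:90332716–90332865, upstream), 2714 at Gls2 and 2303 at Hsd17b13. Pericentral genes had a peak in 12 of 12 with a median of 1337.5 (percentile 95.6), with 2153 at Cyp2e1, 1985 at Rnf43, 1780 at Cyp1a2 and 1652 at Oat. Urea cycle genes had a peak in 8 of 8 with a median of 1523 (percentile 96.0), led by Asl (2734), Arg1 (2507), Nags (2335) and Cps1 (1698). The pericentral and urea lists stayed inside the central 95% of their random lists for promoter height and passed it with promoters of 2.5 kb, at percentiles 98.2 and 98.5. Their distal peaks lay outside it, with medians of 23 (percentile 99.7) and 41.5 (percentile 100), and periportal genes had a median of 29.5 (percentile 99.99).

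Male-biased and female-biased liver genes both lay above the central 95% of their matched random lists. Male-biased genes had a promoter peak in 10 of 10, with a median of 1208.5 (percentile 98.9) and the largest at Cyp2d9 (1944), the repressor gene Bcl6 (1846), Hsd3b5 (1811) and Slco1a1 (1378). Female-biased genes had one in 7 of 11, with a median of 85 (percentile 98.0). The largest were at Acot3 (1182), A1bg (522), Cux2 (169), a female-specific repressor of male-biased genes, and Sult3a1 (119), whereas Cyp2b13 and Cyp3a41a had none. Median numbers of distal peaks were 32 (percentile 99.995) and 9 (percentile 92.9). The difference between the lists was not tested, and the random lists matched to them differed as well, with medians of 106 and 0. Against random lists not matched on CpG content the percentiles fell to 89.4 for the male-biased and 18.4 for the female-biased list. The male-biased list was at 97.4 with promoters of 500 bp, and the female-biased list at 49.5, with a peak in 3 genes, when peaks at or above the median height were used alone.

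Immediate early genes, which respond within minutes to stimuli, had a peak in 10 of 10 promoters with a median of 2015 (percentile 99.4), with 3291 at Jun (4:95052236–95052385, upstream), 2497 at Atf3, 2271 at Dusp1 and 2080 at Junb. Their median number of distal peaks was 24 (percentile 99.2; 97.4 with a 100 kb window). Housekeeping genes had a peak in 13 of 13 with a median of 1808, at percentile 96.5 of the matched lists and 99.5 of unmatched ones. Rpl13a (2892), Eef1a1 (2830) and Gapdh (2461) were among the highest. Their median of 14 distal peaks lay near the middle of the random lists (percentile 58.9).

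**Figure D2:**
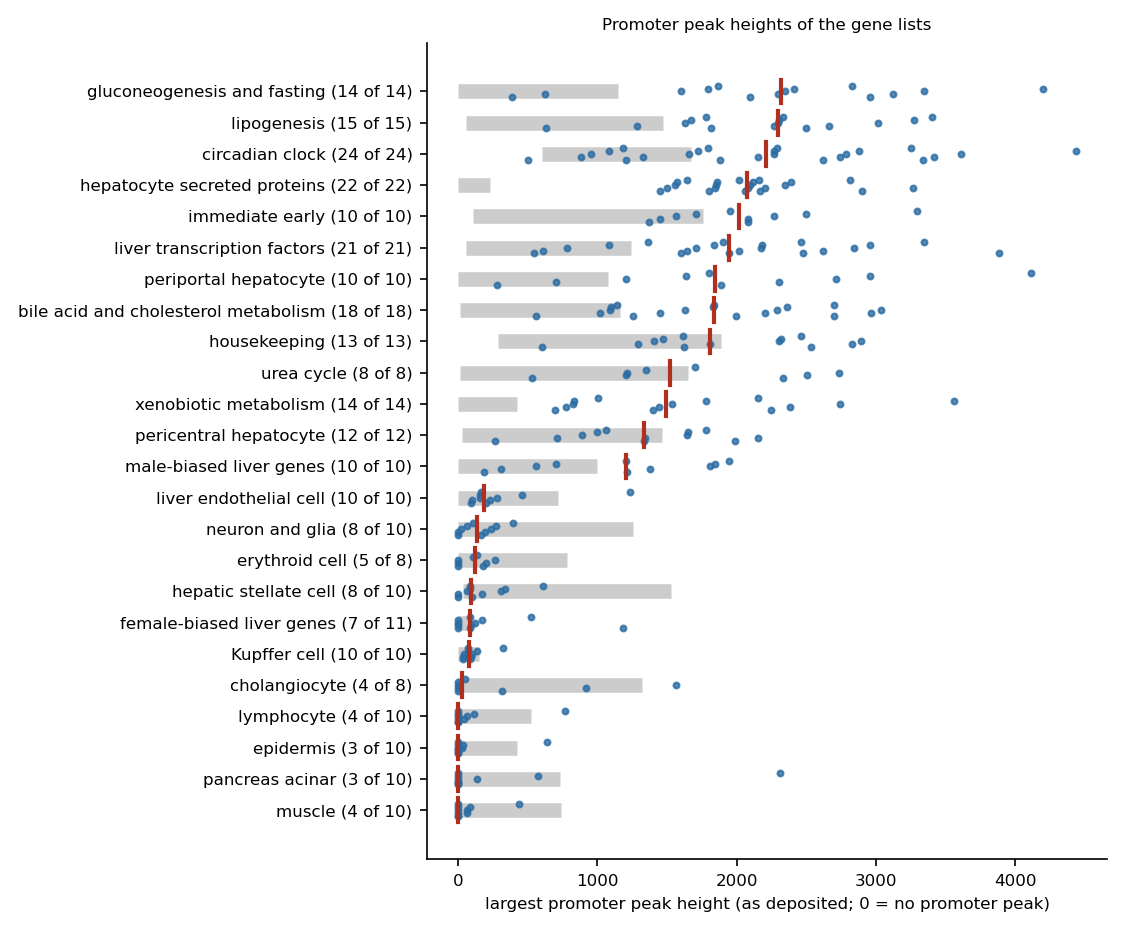
Largest promoter peak height of each gene (points) and the median of each gene list (lines), beside the central 95% of the medians of 10000 matched random lists (grey). The medians of secreted proteins (2071) and the clock (2210.5) lie right of the grey range, those of urea cycle (1523), pericentral (1337.5) and housekeeping genes (1808) lie inside it, and those of other tissues lie within it or at 0.

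Markers of the other cell types of liver had median promoter heights inside the central 95% of their random lists. Its lower bound was 0 for the Kupffer cell, endothelial and cholangiocyte lists, so these could not lie below it. Kupffer cell genes had a promoter peak in 10 of 10 with a median of 78 (percentile 94.4), with 321 at Cd68, 138 at Adgre1, 99 at Cd5l and 93 at Timd4. Endothelial genes had one in 10 of 10 with a median of 185 (percentile 82.5), with 1234 at the hyaluronan receptor gene Stab2 (10:86878856–86879005, coding exon), 458 at Fcgr2b, 277 at Clec4g and 227 at Kdr. Their distal peaks had a median of 19.5 (percentile 98.4; 95.1 with a 20 kb window and 96.9 with the higher peaks). Stellate cell genes had a peak in 8 of 10 with a median of 93 (percentile 8.70), with 608 at Col1a1, 338 at Reln, 307 at Hgf and 173 at Lrat, and none at Acta2 and Ngfr. Cholangiocyte genes had one in 4 of 8 with a median of 26.5 (percentile 14.2). Among these were the transcription factor gene Sox9 (1566), Spp1 (313) and Epcam (53), and Cftr and Cldn4 had none. Distal medians were 8 for Kupffer cell (percentile 73.9), 10 for stellate cell (23.6) and 13 for cholangiocyte genes (71.8). With peaks at or above the median height alone, Kupffer cell genes had a peak in 2 and stellate cell genes in 4. Against unmatched random lists the promoter percentiles were 14.7 for Kupffer cell, 26.5 for endothelial, 16.4 for stellate cell and 8.41 for cholangiocyte genes.

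Blood cell markers had few or low promoter peaks, with medians inside the central 95% of their random lists. Lymphocyte genes had a promoter peak in 4 of 10 (percentile 20.4), at Lck (771), Ptprc (113), Cd2 (68) and Ms4a1 (41), with none at Cd3e. Erythroid genes had one in 5 of 8 with a median of 122.5 (percentile 72.6), among them Alas2 (199), Tal1 (183) and Epor (138), with none at Gata1 and Hbb-b1. Lists of other tissues also stayed inside the central 95%. Its lower bound was 0 for the blood cell and other tissue lists. Even a list without any promoter peak could therefore not lie below it. Muscle genes had a peak in 4 of 10 (percentile 15.2), which were Ckm (436, a peak also within 1 kb of Klc3), Des (89), Tnni2 (65) and Actc1 (62), with none at Acta1 and Mb. Pancreas acinar genes had one in 3 of 10 (percentile 14.9), at Cela1 (2308, 15:100679156–100679305, intron), Rbpjl (572) and Cela2a (138), and not at Cel and Cpa1. Epidermis genes had one in 3 of 10 (percentile 24.6), at Krt10 (640), Trp63 (36) and Krt1 (30), and not at Dsc3 and Dsg3. Neuron and glia genes had one in 8 of 10 with a median of 134 (percentile 35.2), among them Gfap (395), Snap25 (276), Mbp (240) and Rbfox3 (192), with none at Neurod1 and Neurod6. Distal medians of these lists were 9.5 for lymphocyte (percentile 50.9), 10.5 for erythroid (72.3), 9 for muscle (45.1), 11.5 for pancreas (73.5), 6.5 for epidermis (36.9) and 8 for neuron and glia genes (19.0), all inside the central 95% of their random lists. Against unmatched random lists, the promoter percentiles of the lymphocyte, muscle, pancreas and epidermis lists were 2.20, 2.42, 2.24 and 2.39, below the 2.5 bound, and those of the erythroid and the neuron and glia lists 21.5 and 21.1. Promoters of 2.5 kb held a peak in 7 muscle and 6 epidermis genes, and peaks at or above the median height were left at 5 neuron and glia genes and at 1 gene each of the lymphocyte, muscle and epidermis lists.

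The second question was which factor families' sequences were protected. The 511177 footprints (median 9 bp, 6.03 Mb) were set against the rest of the peaks of the second-run permissive list, and each consensus string against up to 20 strings of the same letters in another order. The largest ratios were those of NRF1, a promoter factor, and of the insulator protein CTCF. The NRF1 string GCGCATGCGC was 46.7 times as frequent per base in footprints as outside them (35.6–62.1), the CTCF core 33.8 times (31.9–35.9), the SP/KLF string 13.7 times and the CRE, the site of CREB/ATF factors, 10.5 times. Strings of liver factors had ratios of 8.51 for NFI, 8.50 for HNF1, 6.00 for the PPAR/RXR repeat, 5.47 for ONECUT, 5.43 for HNF4A (5.07–5.82) and 4.13 for CEBP. In each of these but HNF4A no reordered string reached the same ratio, and in HNF4A 1 of 20 did.

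Among strings of the clock, the REV-ERB repeat had a ratio of 3.30 (2.22–4.82), the E-box CACGTG, which CLOCK:BMAL1 and other factors bind, 1.87 (1.78–1.95), the D-box 1.76 (1.62–1.91) and the ROR element 1.37 (1.18–1.59). Reordered strings reached the same ratio in 1 of 11 cases for the REV-ERB repeat, 3 of 20 for the E-box, 1 of 20 for the D-box and 0 of 20 for the ROR element. Those not found in both footprints and the rest of the peaks were left out, so fewer than 20 could be compared for some strings. The interval of the ROR element included 1 against 20 bp flanks (ratio 1.12) and in promoter peaks alone (1.04), and that of the REV-ERB repeat did so in promoter peaks alone (2.99, 0.825–9.12). YY1 (7.23), FXR (4.78), ETS (4.24), NFY (1.89), the neurogenic E-box (1.67), PU.1 (1.48), STAT5 (1.25) and SOX (1.14) also lay above 1, and GRHL (1.17) and the MyoD E-box (1.01) had intervals that included 1. Reordered strings reached the ratio in 0 of 19 cases for YY1, 1 of 10 for FXR, 0 of 20 for PU.1, 1 of 20 each for ETS and SOX, 2 of 20 each for the neurogenic E-box and STAT5, and 3 of 20 for NFY. Below 1 were GATA (0.252, 0.227–0.279), the forkhead string of FOXA (0.347, 0.324–0.371), the glucocorticoid response element (0.452), MEF2 (0.477), RUNX (0.489), OCT (0.647), p53 (0.681) and AP-1 (0.756). All 20 reordered strings of GATA had higher ratios, but the others lay within the range of theirs, with ratios at or above in 15 of 20 each for FOXA, the glucocorticoid response element, RUNX and p53, 9 of 20 each for MEF2 and AP-1, and 4 of 20 for OCT. In distal peaks alone the ratios of promoter strings were lower, at 15.9 for NRF1, 6.37 for SP/KLF, 6.19 for CRE, 4.45 for YY1 and 1.58 for ETS. In promoter peaks alone the intervals of FXR (2.39), PU.1 and the neurogenic E-box (1.13) included 1.

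**Figure D3:**
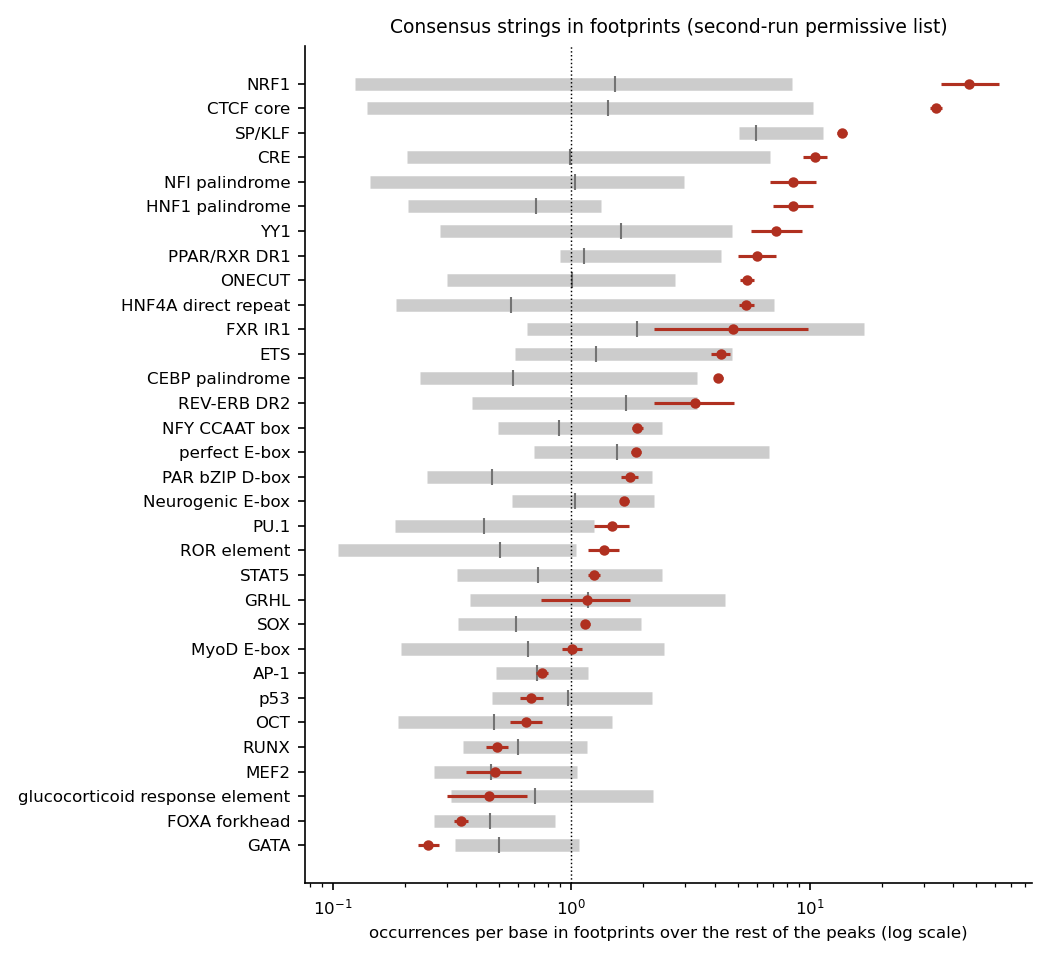
Frequency per base of consensus strings in footprints over the rest of the peaks (points on a log axis, with exact 95% intervals as bars for counting error) and the range and median of their reordered strings (grey bars and ticks). NRF1 (46.7) and CTCF (33.8) lie far right of their grey ranges, and GATA (0.252) lies left of its range.

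Promoter and distal peaks differed in the strings they held. Per kb, most strings of liver factors were more frequent in distal peaks, with distal-over-promoter ratios of 2.14 for HNF1 (1.53–3.08), 1.93 for PPAR/RXR (1.45–2.62), 1.86 for NFI (1.32–2.70), 1.77 for HNF4A (1.59–1.97), 1.77 for FOXA (1.70–1.85), 1.66 for CEBP (1.56–1.77) and 1.12 for ONECUT (1.02–1.24). The FXR string had 1.12 with an interval that included 1 (0.484–3.00), and 6 of 13 reordered strings reached it. Most other strings leaned this way, including 2.41 for the ROR element, 1.97 for CTCF, 1.89 for the REV-ERB repeat, 1.76 for GATA, 1.73 for the D-box, 1.67 for RUNX, 1.61 for AP-1 and 1.55 for p53. Reordered strings with the same letters leaned at least as far in 17 of 20 cases for the D-box, 5 of 15 for HNF1, 1 of 9 for PPAR/RXR, 5 of 20 for CEBP, 2 of 20 each for FOXA and ONECUT and 1 of 20 each for HNF4A, NFI, ROR and RUNX, in 0 of 12 for the REV-ERB repeat and in 0 of 20 for CTCF, GATA, AP-1 and p53. Reordered strings not found in both classes of peaks were left out, so these counts can miss strings that leaned as far. The interval of NFI included 1 with the higher peaks alone (ratio 1.43). Strings of promoter factors went the other way, with 0.0286 for YY1, 0.0454 for NRF1, 0.0867 for SP/KLF, 0.126 for ETS and 0.214 for CRE. All reordered strings of YY1, SP/KLF, ETS and CRE had higher ratios than these, and for NRF1 14 of 19 did. The E-box had a ratio of 0.635 (0.608–0.664), below 1, but above that of all 20 of its reordered strings (median 0.438, highest 0.616).

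Footprints were found mainly in higher peaks. Of the permissive peaks, 72.7% held at least 1 footprint (72.6–72.9), but only 3.79% in the lowest 10% of heights and 99.8% in the highest 10%. Promoter and distal peaks held one about equally often (72.5% and 72.8%), with a mean of 2.20 and 1.72 footprints per peak. Promoter peaks were higher, however, with a median scaled height of 0.864 against 0.417. In the highest 10% of the permissive peaks the shares were 99.8% and 99.7%, with means of 4.40 and 3.69. Of the footprints, 89.2% lay in permissive peaks, 80.5% in stringent peaks, 76.7% in first-run peaks and 98.9% in hotspots, the broader regions of raised cleavage.

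**Figure D4:**
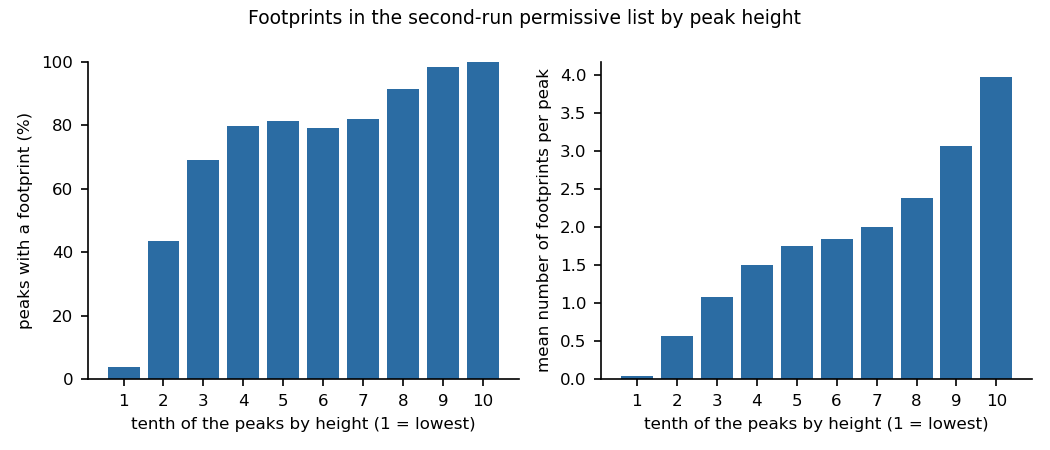
Percent of permissive peaks with at least 1 footprint (left) and mean number of footprints per peak (right) in 10 equal classes of peak height, from the lowest (1) to the highest (10). The share climbs from 3.79% to 99.8% and the mean from 0.0399 to 3.97.

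Among the 10 promoter and 10 distal peaks with the largest heights, 6 lay in 1 segment of chromosome 1 that holds the bilirubin-conjugating gene Ugt1a1, the centromere histone chaperone gene Hjurp and the cold-sensing channel gene Trpm8. The highest there was in an intron of Trpm8 (1:88288216–88288365) and reached 21030. A second Trpm8 intron peak reached 10949 (1:88279236–88279385), 1 peak of 10971 (1:88277556–88277705) lay at the annotated starts of both Hjurp and Trpm8, an intron of Hjurp reached 8619, and Ugt1a1 reached 6561 at its promoter (1:88211836–88211985) and 9548 in an intron (1:88213756–88213905). The segment at 1:88211001–88289000, whose bounds were set after its values were seen, held 53 peaks with a median height of 423, and the next 20 kb held 38 peaks with a median of 47.

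**Figure D5:**
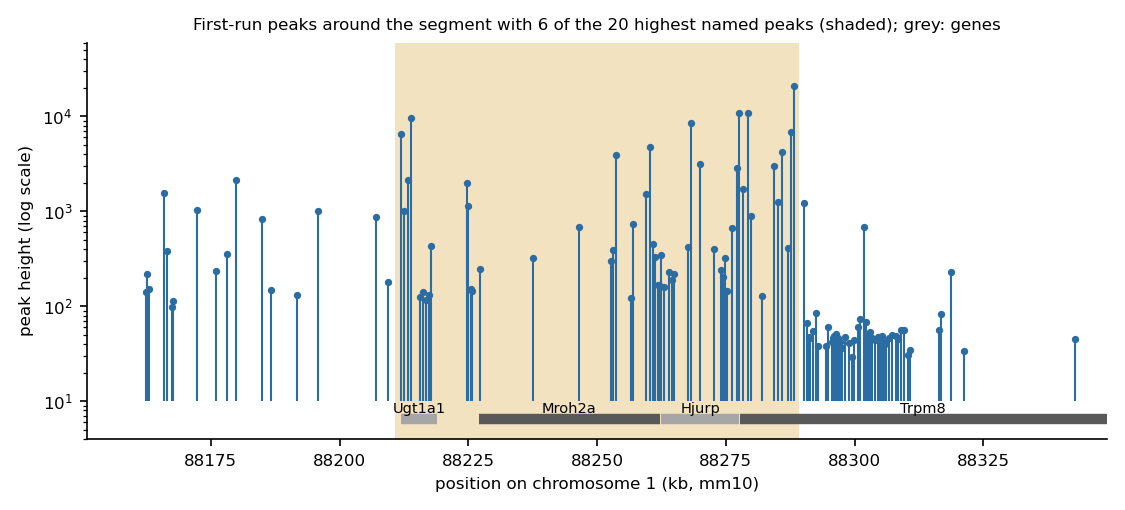
Heights of the peaks (points, log axis, with position in kb) along chromosome 1 around Ugt1a1, Hjurp and Trpm8, with the segment shaded. Heights reach 21030 at its end, and the median falls from 423 inside it to 47 in the next 20 kb.

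The highest peak of all, 22394, lay 589 bp from a start site of the non-coding gene Gm15564 (16:35981656–35981805), in sequence that matched 12 other places of the reference at 90% identity or more over at least 50 bp. The Gm27940 promoter peak (6356) matched 2 others. Promoter peaks without such matches followed at Gm42642 (6285), Ankhd1 (6073), Nop14 (5039), Abhd11 (4969), Slc25a28 (4965) and Snrnp70 (4938). Outside the segment, the highest distal peaks were nearest Ifna13 (17944, intergenic at 4:88641056–88641205), Lars2 (17117, exon at 9:123461916–123462065, with 9 other places), Pak3 (15082, intergenic at X:143482996–143483145, 11 other places), Jarid2 (10225, intron, 14 other places), Gm27679 (9199, intergenic, 3 other places) and Cd209a (7659, intergenic).

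Chromosome X carried 42.8 peaks per Mb, 0.408 of the autosome median of 105, and the median height of its peaks was 0.496 of that of the autosomes. With peaks at or above the median height alone, which were chosen as an alternative after seeing the data, these ratios were 0.251 and 0.837. That cut sets the same lowest height for every chromosome. As X peaks were lower, the cut by itself lowers the density ratio and moves the height ratio towards 1. Chromosome Y carried 165 peaks. Promoter peaks at 4 Y-linked genes with X-linked relatives, named after their values were seen, reached 1394 at Uty, 797 at Ddx3y, 718 at Eif2s3y and 363 at Kdm5d. Sex was not collected per the labels.

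Last, the lists made by the 2 processing runs on the same pooled libraries were compared, which measures the processing and not a repeat of the experiment. Of the first-run peaks, 93.0% (92.9–93.1) overlapped a peak of the second-run permissive list by at least 1 bp, and 95.3% of those 248932 peaks overlapped a first-run peak. The 17879 first-run peaks without a partner were low, with a median height of 44 against 135 for the others. The stringent list of 185762 peaks lay in the first-run list for 97.6% of its peaks and held 70.7% of the first-run peaks. Jaccard indices of covered bases were 0.589 between the first-run and permissive lists and 0.501 between the first-run and stringent lists, in which peaks of 150 bp meet peaks of 200 bp. Heights of 228125 matched peaks had a Spearman rho of 0.999 across peaks, which are not independent replicates. Hotspots, 215247 in number and covering 3.68% of the genome, held 99.999% of the first-run peaks. Both came from the first run, and 100% of hotspots held a first-run peak, so this share does not measure agreement between runs. Of the second-run peaks, hotspots held 96.4% in the permissive and 99.4% in the stringent list. In the tracks of cleavage rate, 84.9 Mb of the first run and 82.8 Mb of the second were below a false discovery rate of 0.01, with a Jaccard index of 0.905, and 87.9% of the first-run peaks held a base below 0.01.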

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

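The basic transcript set, the first-run list for strings in footprints and the alternatives for chromosomes were chosen after seeing the data; the other alternatives named here were planned. Over 159 results and 624 alternatives, 532 values kept their call or stayed within a tolerance, 56 moved past the tolerance, 16 became weaker, 12 stronger and 8 reversed. The tolerance was the exact 95% interval of the first value for shares, Jaccard indices and chromosome densities, and a factor of 1.5 for counts, so counts within it could still differ. Percentiles and string ratios were judged on their call alone. Promoter percentiles kept their side of the central 95% in 133 of 144 alternatives, distal percentiles in 67 of 72, and ratios of strings in footprints kept direction and call in 116 of 128. Unless the setting itself accounts for a shift (fewer peaks, a narrower promoter, a tighter overlap), the cause was not tested.

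With a reciprocal overlap of 50%, 78.7% of first-run peaks and 81.2% of permissive peaks had a partner in the other list, 95.7% of first-run peaks lay in hotspots and 88.0% of footprints in permissive peaks. With peaks at or above the median height the shares with a partner were 96.4% and 99.4%. The promoter share was 19.8% in the permissive list, 22.3% in the stringent list, 25.9% among the higher peaks, 13.1% within 500 bp, 31.0% within 2.5 kb and 16.1% with the basic transcript set. The Jaccard index of the tracks was 0.908 at a threshold of 0.05 and 0.901 at 0.001.

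Promoters of 2.5 kb put the urea cycle list at percentile 98.5 and the pericentral list at 98.2, with a peak in 7 muscle and 6 epidermis genes. Promoters of 500 bp put the male-biased list at 97.4 and left a peak in 4 neuron and glia genes. Against unmatched random lists the percentiles were 89.4 for male-biased, 18.4 for female-biased, 99.5 for housekeeping, 2.20 for lymphocyte, 2.42 for muscle, 2.24 for pancreas acinar and 2.39 for epidermis genes. With the higher peaks alone, the female-biased list fell to percentile 49.5 with a peak in 3 genes, and peaks were left at 2 Kupffer cell, 4 stellate cell, 1 lymphocyte, 1 muscle, 5 neuron and glia and 1 epidermis genes; the stringent list left 1 epidermis gene. For distal peaks, a 20 kb window gave percentiles of 97.9 for female-biased and 95.1 for endothelial genes, the higher peaks gave 99.1 and 96.9, and a 100 kb window gave 97.4 for immediate early genes.

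Strings that changed direction were the MyoD E-box (footprint ratio 0.936 against 20 bp flanks and 0.551 in promoter peaks), SOX (0.951 in promoter peaks), GRHL (0.883 against flanks and 0.963 with the first-run list), and, for distal over promoter peaks, PU.1 (0.978 with the higher peaks) and OCT (0.963 with 500 bp promoters and 0.933 with the higher peaks). Intervals came to include 1 for the footprint ratios of the ROR element (1.12 against flanks, 1.04 in promoter peaks) and, in promoter peaks, of the REV-ERB repeat (2.99), FXR (2.39), PU.1 and the neurogenic E-box (1.13). The same held for the distal-over-promoter ratios of NFI (1.43 with the higher peaks) and, with 500 bp promoters, of PU.1 (1.11) and GRHL (0.703). With the higher peaks the density of X over the autosome median was 0.251, and with the stringent list 0.371.

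No paired analysis was possible because there is 1 group and every deposited list pools both libraries; leaving out each library was not run for the same reason. In the lowest 10% of heights 3.79% of peaks held a footprint, so a missing footprint in a low peak says little about binding.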

Other observations

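Of the tests in this part, those of other reference places for the chromosome 1 segment, of the forkhead string in distal peaks and of shared reads at Y-linked promoters were set out before their results were seen, and the other tests, with the search for strings in clock promoters, were chosen only afterwards.

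Clock promoters held a protected E-box more often than promoters of matched random sets. In 11 of the 24 clock genes a perfect E-box (CACGTG) lay in a footprint of a promoter peak, against a median of 2 (0 to 5) among 10000 random sets of genes matched on the number of promoter footprints (percentile 100). Over all 14614 genes with a promoter footprint, 652 (4.46%) had one. The random sets were not matched on the number of E-boxes in promoter peaks. The excess may thus be one of E-boxes and not of their protection, which was not tested. Among the 15 sites were 2 each at Per1, Dbp, Tef and Ciart, and 1 each at Npas2, Cry1, Nr1d1, Nr1d2, Hlf and Bhlhe41. The Per1 sites lay at 11:69095067–69095072 and 11:69098783–69098788, 147 and 162 bp from annotated start sites, the Dbp sites at 7:45707712–45707717 and 7:45707825–45707830, and the Nr1d1 site at 11:98775695–98775700. The D-box, bound by DBP, TEF, HLF and NFIL3, was protected in Per3 and Nr1d2 (percentile 98.0), at the upper bound of its random sets (median 0, 0 to 2). The CRE was protected in Hlf, Csnk1d and Csnk1e (percentile 95.6), inside its random range of 0 to 3. The ROR element was protected in 0 of the 24 genes, but its random median was also 0 (0 to 1), and 16 of the 14614 genes had one. In Tef 3 of 5 promoter E-boxes, and in Bhlhe40 both, lay outside footprints.

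Distal peaks held the strings of liver factors more often than windows 1 kb away. The ratio was 28.7 for NFI (17.4–50.9), 13.9 for HNF1 (9.96–19.9), 8.20 for HNF4A (7.49–8.99), 3.14 for CEBP (3.02–3.27), 2.30 for ONECUT (2.16–2.45) and 1.54 for FOXA, and no reordered string reached any of these. The insulator string of CTCF had a ratio of 75.0 (63.2–89.7) and the REV-ERB repeat of 10.1. In the highest 10% of distal peaks the ratio of HNF4A was 22.4 (16.2–31.9), that of HNF1 28.2 (10.6–106) and that of CEBP 5.75 (5.05–6.56), with 54.8 (30.3–111) for CTCF and 8.45 (1.88–77.8) for the REV-ERB repeat. Differences from all distal peaks were not tested. Strings of factors best known from other cell types varied. PU.1 of macrophages had a ratio of 3.67 (3.24–4.17), GRHL 2.03 (1.53–2.69), the MyoD E-box 1.82 (1.73–1.92), the neurogenic E-box 1.17, MEF2 1.16 (1.06–1.28) and OCT 0.839. No reordered string reached the ratio of PU.1, the MyoD E-box or MEF2, whereas 2 of 20 reached that of GRHL, 11 that of the neurogenic E-box and 5 that of OCT. In the highest 10% of distal peaks PU.1 had 1.27 (0.785–2.04), MEF2 0.996 (0.699–1.41) and GRHL 2.11 (0.888–5.26), with intervals that included 1, and the MyoD E-box 2.02 (1.71–2.39). There 4 of 20 reordered strings reached the ratio of PU.1, 1 that of MEF2, 5 that of GRHL and 2 that of the MyoD E-box.

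The highest peaks form the first pattern. Other copies in the reference are argued against for the chromosome 1 segment, since 5.66% of its 53 peaks (1.18–15.7) matched another place, against 9.20% of 500 random peaks. Of the 8 highest promoter peaks outside it 2 did so (Gm15564 and Gm27940; 25%, 3.19–65.1), too few peaks to tell, and of the 6 highest distal peaks 4 did, so shared reads are a candidate explanation for those 4. Copies of the segment that the reference lacks may raise its peaks and stay open. The 10th percentile of its heights, 143.4, lay at percentile 98.6 of 285 autosomal windows of equal length with at least 40 peaks each. It lay at 98.2 to 99.4 in 7 other divisions, into windows of 60 to 100 kb with the same lowest number of peaks. Windows with fewer peaks were not compared. The segment's median lay at 96.5, inside the central 95%, and in the others from 93.8 up to the upper bound of that range. The segment's bounds were drawn around high peaks. Strong regulation of Ugt1a1 in liver stays open, and no biological explanation was tested.

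The forkhead and GATA strings form the second pattern, being rarer in footprints than in the rest of the peaks. Base composition may account for the forkhead ratio of 0.347, since 15 of 20 reordered strings had a ratio at or above it and the others lay below. For GATA the ratio of 0.252 lay below those of all 20 of its reordered strings. This cannot decide the question, because GATA was picked for that same low ratio. Base composition thus stays undecided for GATA. Reordered strings keep the letters and the number of CG steps, but not the order of neighbouring bases, which was not tested. A lack of the forkhead string in open chromatin is argued against. Distal peaks held it at 1.54 times the frequency in windows 1 kb away. The highest such ratio among its 20 reordered strings was 0.970. Short residence of these factors on DNA was not tested, nor was any other biological explanation.

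Peaks on the sex chromosomes form the last pattern. Reads shared between Y-linked promoters and their X-linked relatives are argued against, since 8% of the bases of the Y-linked promoter peaks matched elsewhere in the reference, all in 1 peak at Kdm5d. The lowest Y-linked height, at Kdm5d, was 0.283 of the median of the 4 X-linked relatives, which is consistent with tissue of male animals, in whole or in part. Set against its own relative Kdm5c, Kdm5d reached 0.207, below the bound of 0.25 set for the test, while Uty reached 0.767, Ddx3y 0.976 and Eif2s3y 1.15. A mixture of sexes stays open, and sex is not a group of the design, so no biological difference was tested.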
